A study of Mus musculus with 4 samples.

How the data were processed

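The labels describe whole kidneys of newborn mice, dissociated, cleared of debris and dead cells, and loaded on a droplet system with 3′ version 3 chemistry, at 10000 cells per library. Gene by barcode counts were deposited by the authors as 1 matrix per library; the values are whole numbers of UMIs and are not normalised. Per the submitters' processing notes, reads were processed with Cell Ranger 6.0.2 against mm10, and per the file headers the matrices were written by version 6.0.1. The annotation release was not given in the sources used here. The matrices hold 31053 genes. The bisulfite sequencing samples were not analysed here.

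The barcodes in the matrices (25736 and 22543) exceed the number of cells loaded. Kept cells had at least 1000 UMIs, at least 500 genes and under 15% of UMIs from mitochondrial genes, which left 21188 control and 15645 floxed barcodes. Doublets were scored with scrublet in scanpy 1.11.5 for each library. Its automatic threshold marked 2470 control barcodes and 0 floxed barcodes, so it had not worked in the floxed library. The 8% of barcodes with the highest scores were removed from each library instead (1695 and 1252). That departs from the plan and was decided after the automatic calls were seen. Doublets that this score misses remain.

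Both libraries were clustered together without batch correction: 2000 variable genes without mitochondrial, ribosomal, haemoglobin and sex-linked genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (igraph 0.11.9, scikit-learn 1.9.0). The 27 clusters were named from marker lists fixed before the data were examined, by the mean log2 ratio of each list in the cluster over all other cells. The thresholds of that score (at least 0.5, and 0.5 above the next class where that class also reached 0.5) were set after one look at the clusters. Stroma-like cluster 3 lay close to the first threshold, at 0.555, with 0.062 for the next class. Of the clusters, 3 stayed unnamed. Cluster 0 (474 control and 125 floxed cells, best score endothelium at 1.081) and cluster 16 (1118 and 1174, erythroid at 1.266) had low depth and a score under 2. In cluster 4 (281 and 243) progenitor and stroma markers were mixed. Macrophage-like cluster 9 was also shallow, at medians of 1574 and 1397 UMIs, but kept its name with a score of 3.801. Names are given as class-like, since they were rebuilt from expression. Some named clusters were led by cell cycle or immune genes: a stroma-like cluster by Mki67, Nusap1 and Prc1, a progenitor-like cluster had Cenpf and Top2a among its leading genes, and endothelial-like clusters had the interferon-induced genes Rsad2 or Ifi44 among their leading genes. A cluster of 23 endothelial-like cells came from the control library alone. It lay close to the second threshold, at 1.566 with 1.031 for nephron progenitor, and had the progenitor marker Cited1 among its leading genes.

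UMI counts were summed per class and library and expressed as CPM of the class total. The ratio of 2 sums has an exact conditional binomial 95% interval, and a share of cells has a Clopper-Pearson one. Both cover counting error only. With 1 library per genotype no test across animals could be made, so no p-values are given. Genes were described by a rule of size: at least 25 CPM in the library with the higher level and an interval wholly beyond 1.5-fold. Named genes were chosen by a rule fixed before the data were examined. They are the Tet genes, members of the fixed lists, the 10 highest and 10 lowest ratios in progenitor-like cells, and the 5 highest and 5 lowest in committed nephron-like, proximal tubule-like and stroma-like cells. Genes below 0.2 of their level in another class were left out of the named ones, to avoid free RNA, as were mitochondrial, ribosomal, haemoglobin and sex-linked genes and predicted genes. Some genes that the rule names are not reported here. A ratio against a count of 0 uses a floor of 3 counts.

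The fixed gene lists cover progenitor regulators, commitment, the Wnt, Notch and FGF pathways, DNA methylation enzymes, imprinted genes, germline genes, proliferation, p53 and apoptosis, dissociation stress, glycolysis and hypoxia, oxidative phosphorylation, tubule injury, interferon response and sex-linked genes. The median log2 ratio of the members with at least 5 CPM is given with its percentile among 10000 random lists of the same size matched on mean expression, as a description of these libraries. The sex-linked genes served to compare the animals: Xist was present in both libraries (892 and 785 CPM), and of 4 Y-linked genes 1 UMI was found, in the control. Cycling cells were counted after thinning each cell to 2000 UMIs, leaving out shallower cells. For the alternative that leaves cycling cells out, they were called without thinning.

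The calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Gene coordinates are from a RefSeq table of GRCm38, matched by symbol for 40 of 41 named genes. The size rule was tested on simulated counts drawn from the class sums, with 200 genes changed by 2-fold or 4-fold, 100 each. In progenitor-like cells (4912 genes) it recovered 99 of 100 at 2-fold and 99 at 4-fold. In committed nephron-like cells (5272 genes) it recovered 99 and 100, in proximal tubule-like cells (5128 genes) 95 and 99, and in stroma-like cells (5175 genes) 100 and 100. It made 0 false calls in each of the 4 classes, and the intervals covered the true ratio for 95.3% to 95.5% of genes. The simulated counts held counting error only, the kind that the interval assumes, and no differences between animals, in dissociation or in free RNA. These figures therefore check the calculation and do not say how many calls in the real libraries are false.

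The alternatives were other cell filters, the 10000 deepest barcodes, doublets kept, another clustering resolution, floxed cells mapped to control clusters, TMM factors from edgeR 4.0.16, means of single-cell CPM, thinned cells, cycling cells left out, other thresholds, values relative to stroma-like cells and other denominators. The automatic doublet threshold, the mixed cluster counted as progenitors and cycling shares without thinning were added after the data were seen. So were all alternatives for cycling shares, for shares other than those of progenitor-like, committed nephron-like and stroma-like cells, and for gene counts other than those of progenitor-like cells.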

Results

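Whole kidneys of newborn mice were dissociated and profiled by droplet single-cell RNA sequencing in 2 libraries. One came from a mouse carrying Six2Cre, a recombinase expressed in Six2-positive nephron progenitors, and served as the control. The other came from a mouse with Six2Cre and floxed alleles of Tet2 and Tet3, and is called the floxed library here. Each genotype had 1 library, so no difference below has a replicate check, and every interval covers counting error only. The series also holds 2 bisulfite sequencing samples of sorted progenitors, which were not analysed here. The control matrix held 25736 barcodes and 197745868 UMIs (unique molecular identifiers, which stand for single RNA molecules), and the floxed matrix held 22543 barcodes and 115427704 UMIs. After filtering, 19493 control cells with a median of 5993 UMIs and 14393 floxed cells with a median of 4781 UMIs were kept.

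The first comparison asked how the transcripts of the targeted genes differed between the libraries in the cells that Six2Cre reaches and in those it does not. Tet3, which encodes a dioxygenase that oxidises 5-methylcytosine, was lower in the floxed library throughout the nephron lineage. In nephron progenitor-like cells it stood at 90.7 CPM (counts scaled to a fixed total per class and library) in the control and 41.7 CPM in the floxed library, 2.17-fold lower (95% interval 1.96 to 2.41). It was 2.08-fold lower in committed nephron-like cells, 1.91-fold in podocyte-like cells, 1.82-fold in loop of Henle and distal tubule-like cells and 1.66-fold in proximal tubule-like cells. Outside the lineage Tet3 was also lower, but by less: 1.30-fold in stroma-like, 1.25-fold in ureteric bud and collecting duct-like, 1.32-fold in endothelial-like and 1.35-fold in macrophage-like cells. The log2 ratio in progenitor-like cells minus that in stroma-like cells was -0.75 (-0.93 to -0.56).

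Tet2 encodes a related dioxygenase and differed little. It stood at 27.5 and 21.7 CPM in progenitor-like cells, 1.27-fold lower in the floxed library (1.09 to 1.47), and at 44.0 and 39.1 CPM in stroma-like cells. Its progenitor value minus its stroma value was -0.17 (-0.41 to 0.08), an interval that includes 0. In macrophage-like cells, which Six2Cre does not reach, Tet2 stood at 58.9 and 29.5 CPM. Tet1, the family member that was not targeted, stood at 31.1 and 29.4 CPM in progenitor-like cells and at 31.7 and 41.5 CPM in stroma-like cells. The libraries count tags near the 3′ ends of transcripts. A tag outside the deleted part of a gene can remain after deletion, so these levels do not check the genotype. In GRCm38, which UCSC names mm10, Tet3 (ENSMUSG00000034832) lies on chromosome 6 from 83362373 to 83457208, and Tet2 (ENSMUSG00000040943) on chromosome 3 from 133463677 to 133545136.

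**Figure D1:**
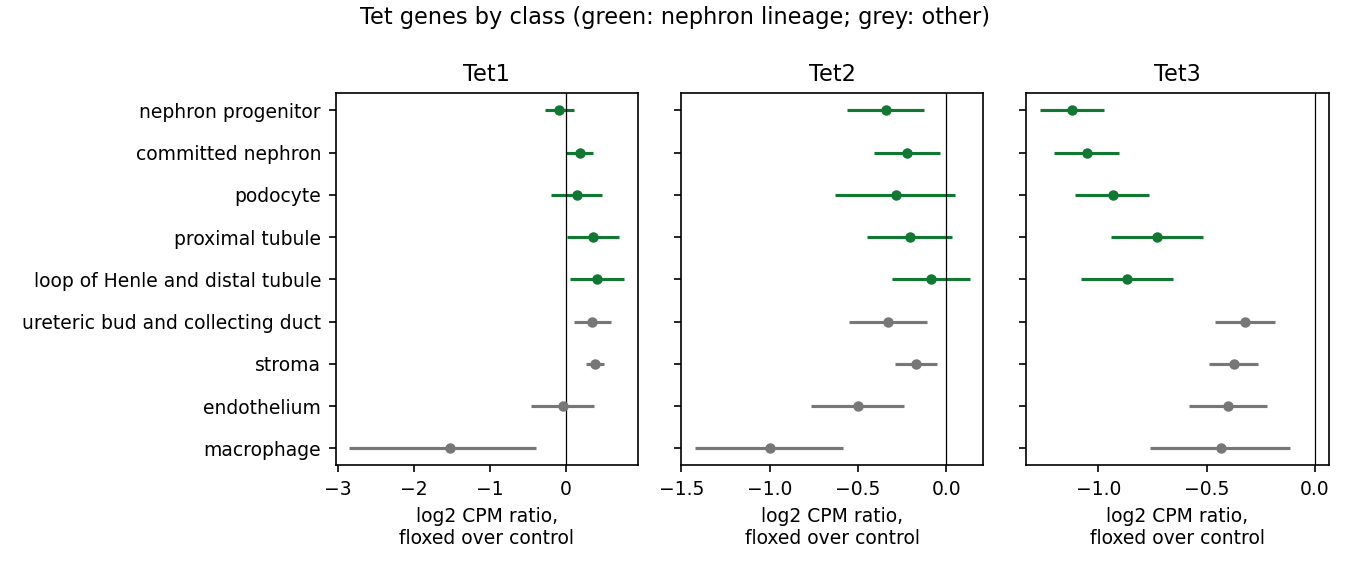
Log2 ratio of the CPM of Tet1, Tet2 and Tet3 in the floxed over the control library for each cell class (vertical axis), with 95% intervals for counting error as lines; green marks the nephron lineage and grey the other classes. For Tet3 the nephron progenitor-like point lies at -1.12 and the stroma-like point at -0.37.

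The second comparison concerned the make-up of the kidney. Nephron progenitor-like cells made up 13.2% of the kept control cells (12.8 to 13.7, Clopper-Pearson) and 10.8% of the floxed cells (10.3 to 11.4). The class held 2 clusters in different proportions: cluster 18 made up 9.94% and 9.16% of the kept cells, and cluster 20, with the cell cycle genes Cenpf and Top2a among its leading genes, 3.30% and 1.67%. Gene levels and cycling shares of the class therefore mix these clusters differently in the libraries. Committed nephron-like cells, which express Lhx1 and Pax8, made up 9.18% and 8.73%. Podocyte-like cells, the filtration epithelium of the glomerulus, made up 5.15% and 4.15%, and proximal tubule-like cells 4.10% and 4.02%. Loop of Henle and distal tubule-like cells made up 2.11% of the control and 3.59% of the floxed cells, and ureteric bud and collecting duct-like cells 4.17% and 6.80%. Stroma-like cells made up 31.2% and 32.2%. Endothelial-like cells made up 15.01% and 10.8%, macrophage-like cells 3.65% and 4.16%, neutrophil-like cells 0.600% and 0.938%, and erythroid-like cells 0.703% and 2.30%. Mural and renin cell-like cells made up 1.25% and 0.792%.

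Within the nephron lineage alone, progenitor-like cells made up 39.2% of the control and 34.6% of the floxed cells, and committed nephron-like cells 27.2% and 27.9%. Clusters left unnamed held 9.61% of the control and 10.7% of the floxed cells, and 1 of them, with 281 control and 243 floxed cells, mixed progenitor and stroma markers. The others, unnamed for low depth, scored best as endothelium (2.43% and 0.868% of kept cells) and as erythroid (5.74% and 8.16%). The endothelial-like and erythroid-like shares depend on leaving them out. Cells with at least 2 UMIs of Six2, the transcription factor that maintains progenitors, made up 3.64% of the control and 2.29% of the floxed cells. Such a count depends on depth: 20.1% of control and 14.4% of floxed progenitor-like cells reached it, at median depths of 7673 and 6229 UMIs. Among endothelial-like cells, which should lack Six2, the shares were 0.513% and 0.0643%, at median depths of 4452 and 3349 UMIs. The control cells of that class include a cluster of 23 cells that also scored for progenitor markers. Shares depend on dissociation and on the filters: with only the 10000 deepest barcodes of each library, progenitor-like cells made up 16.3% and 7.82%, and the direction turned for podocyte-like cells, at 3.28% and 4.43%. That setting cut the libraries at unlike depths, 6824 UMIs in the control and 4134 UMIs in the floxed library, which can itself shift shares. Stroma-like cells made up 20.2% and 26.7% with those barcodes, and 21.6% and 16.4%, the other direction, with the looser cell filter. Proximal tubule-like cells made up 2.73% and 1.72% when floxed cells were mapped to control clusters and 7.52% and 4.95% with the looser cell filter. With the stricter filter the direction turned (log2 ratio, floxed over control, of 0.34). With the looser filter loop of Henle and distal tubule-like cells made up 4.30% and 4.54%.

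**Figure D2:**
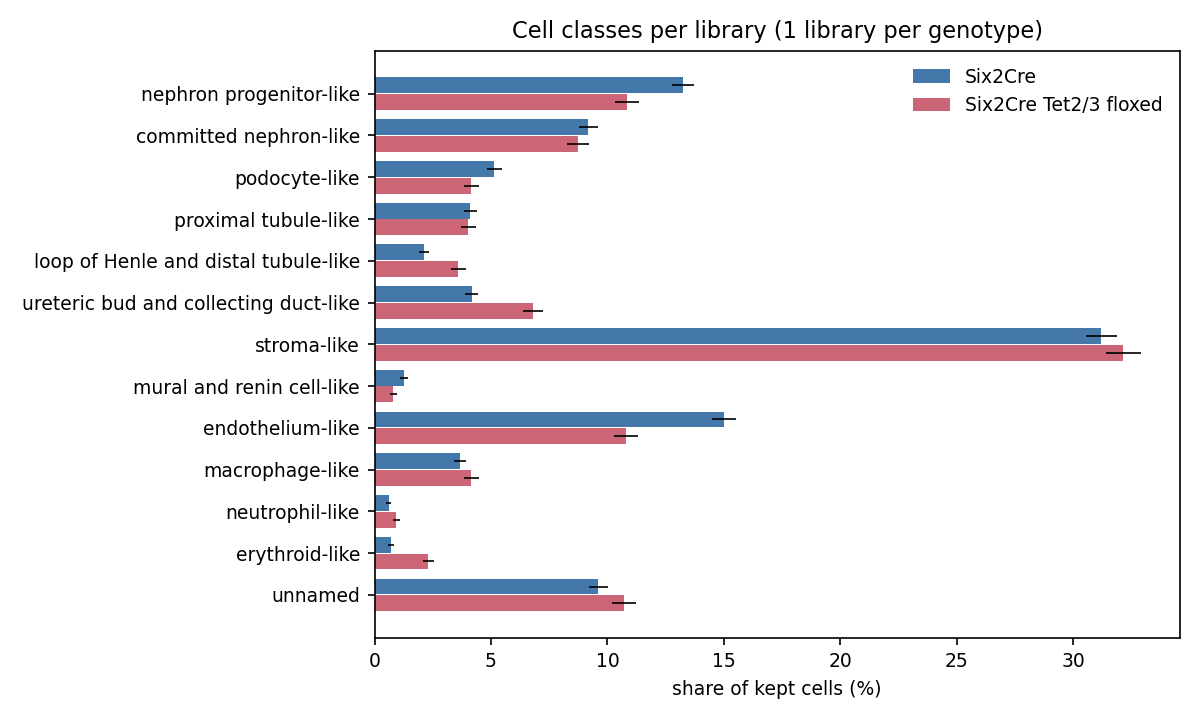
Share of kept cells (horizontal axis, percent) in each cell class for the control and the floxed library, with Clopper-Pearson 95% intervals as lines. Endothelial-like cells stood at 15.01% and 10.8%, and ureteric bud and collecting duct-like cells at 4.17% and 6.80%.

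The third comparison looked at gene levels in nephron progenitor-like cells, which Six2Cre targets, against stroma-like cells, which do not come from Six2-positive progenitors. In progenitor-like cells 111 genes were higher and 70 were lower in the floxed library by a size rule: at least 25 CPM in the library with the higher level, and a 95% interval wholly beyond 1.5-fold. Il33, a cytokine of the interleukin-1 family, stood at 50.6 and 196 CPM, 3.88-fold higher in the floxed library (3.62 to 4.16). Rnase4, a secreted ribonuclease, was 7.35-fold higher (7.72 and 56.7 CPM), and Shisa3, an antagonist of Wnt and FGF receptors, was 2.40-fold higher (39.8 and 95.7 CPM). The immediate early gene Fos was 3.71-fold lower (783 and 211 CPM), and the immediate early genes Nr4a1 and Egr3 were 3.26-fold and 2.97-fold lower.

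Other genes at the low end were Myof, a membrane repair protein, 6.39-fold lower (31.3 and 4.90 CPM), and Anxa3, a phospholipid-binding annexin, 3.27-fold lower (56.2 and 17.2 CPM). Stat3, a transcription factor downstream of cytokine receptors, was 2.56-fold lower, the phosphodiesterase gene Pde10a 3.15-fold lower, and the non-coding RNA gene Snhg9 3.01-fold lower. Kcnmb2, a potassium channel subunit, was 4.38-fold higher and Prr5l 2.36-fold. AY036118 was 3.59-fold higher, but it was higher in every class compared (log2 ratios from 1.56 to 2.08). It was also among the leading genes of cluster 16, which stayed unnamed for low depth. Ralyl had 1 UMI in the control and 370 UMIs in the floxed library, a ratio of 856 with an interval from 153 to 33900. In stroma-like cells Ralyl stood at 0 and 1.60 CPM, the same direction at a low level to which free RNA can add. Tpm3-rs7 (27.1-fold higher), Eif3j2 (6.35-fold higher) and Rnaset2b (13.6-fold lower) each have a near-identical copy elsewhere in the genome, so how reads were assigned between copies is uncertain. Crym also passed the rule, but it was among the leading genes of the clusters called progenitor-like and its level is not read as a result.

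Much of this difference was shared with stroma-like cells. Of the progenitor genes past the rule, 40 of the 111 higher and 38 of the 70 lower genes passed it the same way in stroma-like cells. Fos had a log2 ratio of -1.89 in progenitor-like and -1.65 in stroma-like cells, and Il33 1.96 and 0.93. By contrast, Stat3 had -1.36 and -0.12, Anxa3 -1.71 and -0.31, and Rnase4 2.88 and 0.24. A difference that stroma-like cells lack can still occur elsewhere outside the lineage: Rnase4 had 2.51 in ureteric bud and collecting duct-like cells (15.5 and 88.0 CPM), and Stat3 had -0.79 in macrophage-like cells. The difference from stroma-like cells itself lay wholly beyond 1.5-fold for 11 of the higher and 5 of the lower genes. Scaling by TMM factors turned the balance of higher and lower genes in progenitor-like cells, to 89 higher and 94 lower.

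**Figure D3:**
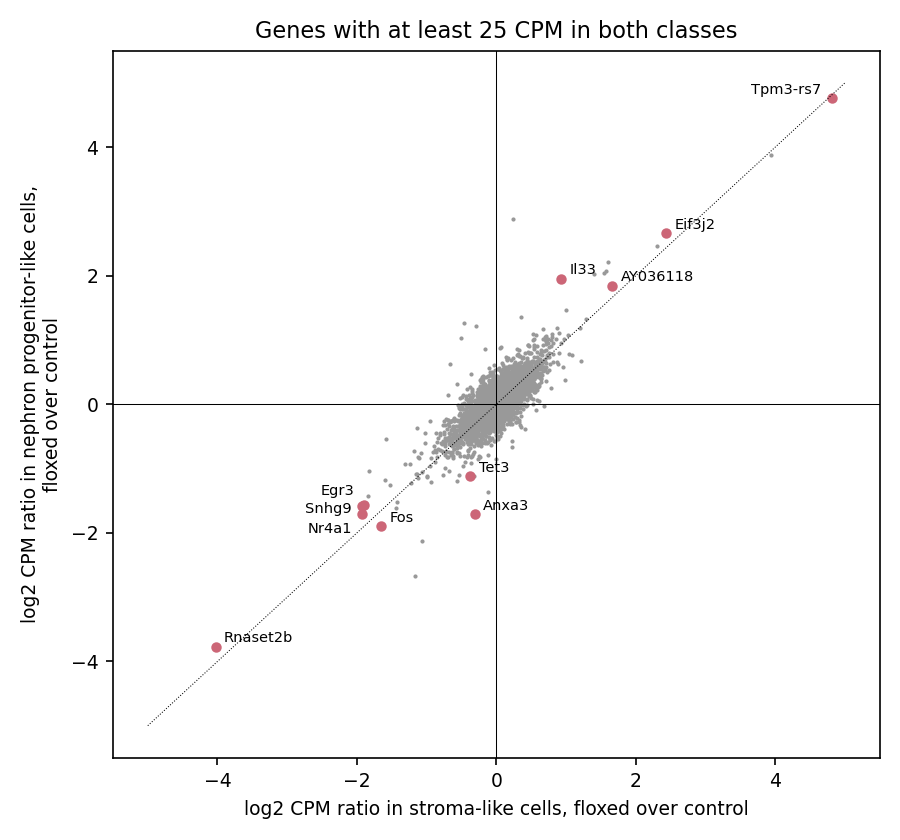
Log2 CPM ratio, floxed over control, in stroma-like cells (horizontal axis) and nephron progenitor-like cells (vertical axis) for 4703 genes, 1 point each; the dotted line marks equal ratios. Tpm3-rs7 (4.76 in progenitor-like cells) and Rnaset2b (-3.77) lie near that line, and Tet3 (-1.12) and Anxa3 (-1.71) below it.

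Gene groups in progenitor-like cells. Of 19 measured progenitor regulators, 1 passed the rule: Osr1, an early transcription factor of the lineage, stood at 27.4 and 50.2 CPM, and the median log2 ratio of the list was -0.01 (percentile 27.9 among 10000 random lists matched on expression). Sall1 stood at 74.4 and 112 CPM, and Hoxa11 at 43.1 and 69.0 CPM, short of the rule. Several members of this list, such as Six2, Cited1 and Eya1, also led the clusters called progenitor-like, which limits what the median can show. Of 14 measured commitment genes none passed the rule, 12 had a positive log2 ratio, and the median was 0.35 (percentile 99.1), against 0.29 in stroma-like cells. It was 0.14 with the 10000 deepest barcodes and 0.55 with the automatic doublet threshold. In progenitor-like cells 3 of these 14 members reached 0.2 of their level in the class where they were highest. Wnt4, which drives the transition from mesenchyme to epithelium, stood at 581 and 595 CPM, and Lhx1 at 35.2 and 50.3 CPM. Wnt4 was among the leading genes of cluster 20, so its class level depends on how much of the class that cluster made up. The Wnt pathway list had a median of -0.03 and the FGF response list 0.05 (percentiles 22.0 and 47.3), and the Wnt median kept its sign in 4 of 11 alternatives. The Notch pathway list had a median of 0.23 (percentile 89.7), with none of 7 members past the rule. Of 13 DNA methylation enzymes, Tet3 was lower and Gadd45g, a stress-response gene, was higher (18.0 and 35.0 CPM); the median was -0.15 (percentile 3.72), but 0.032 without cycling cells and near 0 with Leiden resolution 0.5. The imprinted list had a median of 0.20 (percentile 96.9) and no member past the rule; Peg3 stood at 639 and 431 CPM and Kcnq1ot1 at 302 and 414 CPM.

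Of 11 measured dissociation stress genes, 6 were lower in progenitor-like cells, among them Egr1 (1040 and 470 CPM) and Jun (682 and 349 CPM), and the median was -0.97. In stroma-like cells 9 of 11 were lower, with a median of -1.15. The list had a median of 0.27 in podocyte-like cells (percentile 99.8) and 0.26 in proximal tubule-like cells (percentile 98.7), with 1 member higher in each, and of -0.11 in committed nephron-like, -0.18 in endothelial-like and -0.22 in macrophage-like cells. Of 5 measured interferon response genes, 4 had negative ratios, none passed the rule, and the median was -1.61. In stroma-like cells that list had a median of -2.19, with 5 of 10 members lower, and Bst2, which tethers virions at the cell surface, stood at 125 and 38.5 CPM. The proliferation list had a median of -0.31 in progenitor-like and -0.23 in stroma-like cells, with none of its 20 members past the rule in either. The same list had -0.65 in ureteric bud and collecting duct-like cells, with 6 members lower. It had -0.36 in loop of Henle and distal tubule-like cells, with 3 lower, and -0.07 in committed nephron-like cells. The progenitor median was 0.02 with the 10000 deepest barcodes and -0.10 with Leiden resolution 0.5, so it was not stable. Without cycling cells it was 0.26, but the cells left out were chosen by proliferation genes, so that value decides nothing. They were called without thinning and made up 53.3% of control and 32.8% of floxed progenitor-like cells. Members of the list had both signs: the mitotic gene Top2a stood at 297 and 204 CPM and the replication gene Mcm3 at 52.9 and 70.0 CPM. The tubule injury list had a median of -0.63, with none of 5 members past the rule and 0 at 0.2 or more of their highest class. The p53 and apoptosis list (-0.06), the glycolysis and hypoxia list (0.04) and the oxidative phosphorylation list (-0.05) had medians near 0. Fewer than 3 germline genes reached the minimum level. RNA of other cell types differed between the libraries in these same cells: proximal tubule markers had a median of -1.08 in progenitor-like and -1.13 in stroma-like cells, endothelial markers -1.03 and -0.84, and erythroid markers 2.07 and 1.54.

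**Figure D4:**
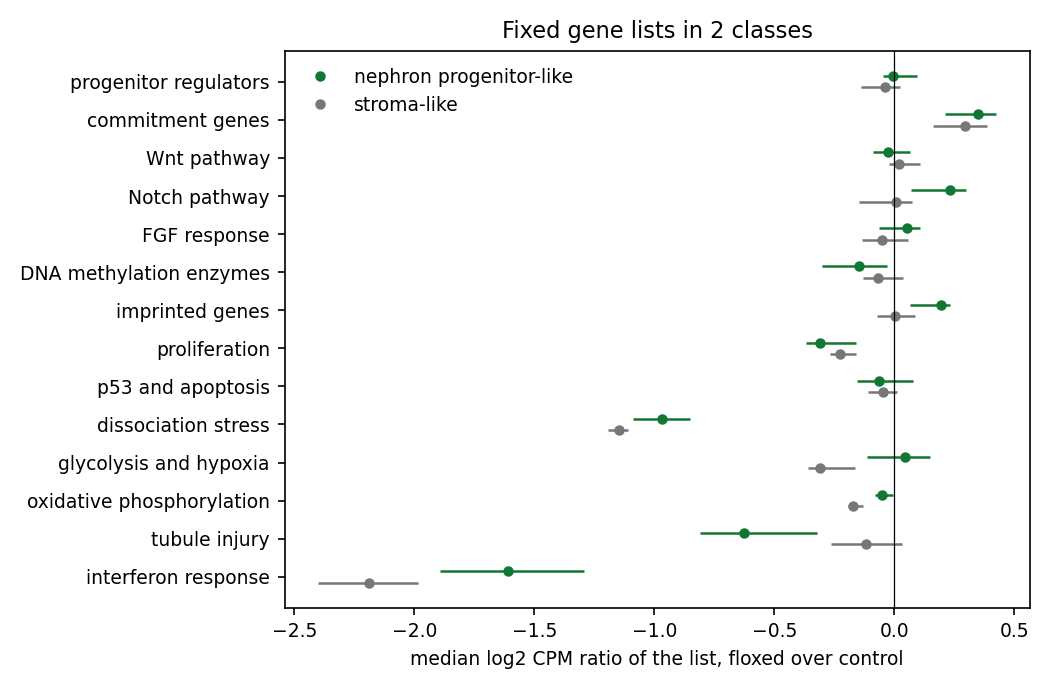
Median log2 CPM ratio, floxed over control, of each fixed gene list (vertical axis) in nephron progenitor-like (green) and stroma-like (grey) cells; lines show 95% intervals for counting error. The dissociation stress list lies at -0.97 and -1.15, and the interferon response list at -1.61 and -2.19.

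In committed nephron-like cells, the pretubular aggregates and early nephron epithelium, 92 genes were higher and 54 lower. S100a6, a calcium-binding protein, stood at 69.0 and 427 CPM, 6.19-fold higher in the floxed library (5.85 to 6.54), and the epithelial keratin gene Krt19 was 3.62-fold higher (13.3 and 48.0 CPM). Acer2, an alkaline ceramidase, was 3.31-fold higher. Serpina6, which encodes the corticosteroid-binding globulin, had 970 UMIs in the control and 1 UMI in the floxed library, a ratio of 495 with an interval from 88.6 to 19555. Serpina6 was also among the leading genes of 1 of the clusters in this class. In stroma-like cells Serpina6 went the same way, at 3.19 and 0.130 CPM, low levels to which free RNA can add. Rpgrip1 was 5.41-fold lower, and lower still in stroma-like cells (log2 ratio -2.44 here and -3.03 there), and Lpl, the lipoprotein lipase, 2.57-fold lower. Tpm3-rs7, Eif3j2, Rnaset2b and Snhg9 differed as they did in progenitor-like cells. Of the genes past the rule in this class, 29 of the 92 higher and 26 of the 54 lower ones passed it the same way in stroma-like cells. Ureteric bud and collecting duct markers, which include Krt19, had a median of 0.72 in this class.

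In committed nephron-like cells 1 of 10 Notch pathway members and 2 of 20 Wnt pathway members passed the rule, and both lists held members of either sign. The Notch list had a median of -0.35, at percentile 0.02 of its random lists, with 4 positive and 6 negative members. Notch1, the receptor, was lower at 123 and 74.9 CPM, and the target gene Hes1 stood at 313 and 232 CPM. The ligand gene Jag1 went the other way, at 57.8 and 79.2 CPM. The Wnt list had a median of 0.20 (percentile 99.4), with 11 positive and 9 negative members: Dkk1, a secreted Wnt inhibitor, was higher at 13.9 and 35.9 CPM, and Lgr5, a receptor for R-spondins, at 21.7 and 41.4 CPM. The commitment list had a median of 0.29 (percentile 99.97) with 3 of 16 members higher and 1 lower (Osr2, at 124 and 74.1 CPM). Osr2 was among the leading genes of a cluster in this class. The higher ones included Irx1 (51.5 and 90.5 CPM) and Pou3f3 (37.4 and 62.0 CPM), transcription factors of the early nephron. Most commitment genes, Osr2 and Pou3f3 among them, were also markers used to name this class, which limits what the median can show. The same list had 0.29 in stroma-like, 0.49 in podocyte-like, 0.45 in proximal tubule-like and 0.01 in ureteric bud and collecting duct-like cells. No alternative processing was run for list medians in committed nephron-like cells. The tubule injury list had a median of 0.37, with Spp1, which encodes osteopontin, higher at 67.8 and 159 CPM.

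Podocyte-like cells were not among the classes chosen for gene comparisons before the data were examined, and their values were looked at afterwards. Nphs1, which encodes nephrin, stood at 412 CPM in the control and 175 CPM in the floxed library, and Podxl, which encodes podocalyxin, at 678 and 401 CPM. The phosphatase gene Ptpro stood at 182 and 169 CPM, and Clic5, a chloride intracellular channel gene, at 183 and 204 CPM. Of the other markers of this class, Synpo stood at 90.4 and 60.1 CPM, Rasl11a at 404 and 273 CPM and Tdrd5 at 28.2 and 9.31 CPM. Over the whole class Clic5 was thus the only one of these markers that was higher in the floxed library. Cdkn1c, an inhibitor of cyclin-dependent kinases, stood at 2714 and 1330 CPM, and Rhpn1, which encodes rhophilin 1, at 150 and 9.31 CPM. The class held 2 clusters in different proportions. Cluster 5, led by Pcp4, had 550 control and 500 floxed cells, and cluster 11, led by Nphs1, had 453 and 97. Within cluster 11 Nphs1 stood at 1116 and 743 CPM and Podxl at 1623 and 1499 CPM. Rasl11a (730 and 463 CPM) and Tdrd5 (80.4 and 49.2 CPM) were also lower there, but Synpo (205 and 215 CPM) and Ptpro (398 and 423 CPM) were not. Within cluster 5 Synpo stood at 35.5 and 36.1 CPM, Ptpro at 79.4 and 129 CPM, Nphs1 at 75.4 and 87.5 CPM and Podxl at 226 and 231 CPM. Nphs1, Podxl, Rhpn1 and Ptpro were among the leading genes of cluster 11, so its size and their levels within it depend on each other. The class levels given above also rest on the mix of the 2 clusters.

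In proximal tubule-like cells 115 genes were higher and 139 lower. Of these, 19 of the higher and 27 of the lower ones passed the rule the same way in stroma-like cells. Stroma markers had a median of -1.09 in proximal tubule-like cells, with 4 of 10 lower. Miox, which encodes the myo-inositol oxygenase of proximal tubules, was 6.75-fold lower in the floxed library (79.0 and 11.7 CPM), and Hsd17b2, a steroid dehydrogenase, 8.88-fold lower (32.7 and 3.68 CPM). Fitm1, a protein of lipid droplet formation, was 8.24-fold lower, and Defb19, a defensin, 6.74-fold lower. Hsd3b2, another steroid dehydrogenase, was 49.5-fold higher (2.53 and 125 CPM), Trh, the thyrotropin-releasing hormone precursor, 12.4-fold higher and Serpina1b, an alpha-1-antitrypsin gene, 4.31-fold higher. Each of these named genes went the same way in stroma-like cells, at low levels to which free RNA can add. Hsd3b2 stood there at 0.0503 and 2.34 CPM, and Miox at 2.56 and 0.130 CPM. Tpm3-rs7, Eif3j2 and Rnaset2b again differed. Of the 14 markers of this class, 3 were lower, Miox among them, and 1 was higher, and 11 had negative log2 ratios. The endocytic receptor gene Lrp2 stood at 691 and 615 CPM and the phosphate transporter gene Slc34a1 at 609 and 652 CPM, and the median of the markers was -0.16. The balance of higher and lower genes turned with TMM factors (133 higher, 116 lower), the stricter cell filter (110 and 106) and the looser one (124 and 118).

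Stroma-like cells, used as a comparator because Six2Cre should not reach them, had 83 genes higher and 104 lower. The class mixed its clusters differently in the libraries: of the kept cells, cluster 3 made up 3.46% and 5.66%, cluster 2 6.65% and 8.55%, cluster 8 7.57% and 6.20%, and cluster 10, led by the proliferation gene Mki67, 6.35% and 4.79%. Gene levels, differences from this class and its cycling share rest on that mix. Ctgf, a matricellular growth factor, was 3.52-fold higher in the floxed library (12.7 and 44.6 CPM), and the germ cell gene Rbm46 13.2-fold higher (4.83 and 63.8 CPM). The interferon-induced gene Ifi27l2a was 6.51-fold lower (250 and 38.4 CPM), and Ppp1r14a, an inhibitor of myosin phosphatase, 4.23-fold lower. Nr4a1 (60.8 and 16.0 CPM), Snhg9 (102 and 26.8 CPM), AY036118 (3.17-fold higher), Tpm3-rs7, Eif3j2 and Rnaset2b differed as in the nephron lineage. The number of genes past the rule was thus 187 in stroma-like and 181 in progenitor-like cells, while 4630 to 6086 stroma-like and 1560 to 2582 progenitor-like cells went into the sums.

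Cycling cells were less frequent in the floxed library within each of 7 classes examined, inside and outside the nephron lineage. With each cell thinned to 2000 UMIs, cells with at least 2 of 8 mitotic genes made up 25.9% of control (24.2 to 27.6) and 17.7% of floxed progenitor-like cells (15.8 to 19.7). Without thinning the shares were 53.3% and 32.8%, and thinning left out 15 control and 13 floxed cells. The thinned shares were 54.0% and 42.4% in committed nephron-like, 25.4% and 18.6% in stroma-like, 31.0% and 24.1% in endothelial-like, 19.1% and 10.6% in ureteric bud and collecting duct-like, 9.29% and 6.28% in podocyte-like and 8.13% and 4.42% in proximal tubule-like cells. Free RNA of mitotic genes can add to such calls, so the difference between the libraries remains open to it. The share of progenitor-like cells in cluster 20, led in part by cell cycle genes, differed between the libraries as given with the class shares. The summed proliferation list stood at 1610 and 1356 CPM in progenitor-like cells and at 1639 and 1396 CPM in stroma-like cells.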

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

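Of the tests in this part, those on interferon response genes and on genetic background were chosen after the results were seen, and only the one on pairs of gene copies was set before its result. Among progenitor-like, committed nephron-like, proximal tubule-like and stroma-like cells, a few genes passed the size rule in opposite directions; none of these differences was tested, as each genotype has 1 library. The genes given here come from those 4 classes only, and others occur beyond them, such as Pde10a with -1.66 in progenitor-like and 1.38 in loop of Henle and distal tubule-like cells. Anxa3 had a log2 ratio (floxed over control) of 1.17 in committed nephron-like and -1.71 in nephron progenitor-like cells. Spp1 had 1.23 in committed nephron-like, -1.60 in proximal tubule-like and -0.93 in stroma-like cells. Gadd45b, a stress-response gene, had 1.24 in proximal tubule-like and -1.59 in stroma-like cells.

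Interferon response genes had negative list medians in all 9 classes compared. Action of the deletion within the nephron lineage alone is argued against, since the highest of the medians in stroma-like, endothelial-like and macrophage-like cells, outside the lineage, was -1.81. Free RNA from another class may add to the level in progenitor-like cells: a first test on whole lists argued against it (-2.20 in macrophage-like and -1.61 in progenitor-like cells), but the measured members differed between the classes, and after that result was seen it was replaced by the 5 members measured in both, with -1.87 (-2.15 to -1.53) and -1.61 (-1.91 to -1.32). The ratios of those 5 were not alike across classes, from -1.03 in ureteric bud and collecting duct-like to -2.13 in proximal tubule-like cells, and Xaf1 (13.8 and 14.4 CPM in progenitor-like cells) did not follow, so in progenitor-like cells free RNA and the cells' own RNA cannot be told apart; it leaves open why macrophage-like cells themselves differed, with Ifit3 at 196 and 5.91 CPM. An interferon response of the single control animal or litter stays open, and the stroma-like median of -2.19 cannot be told apart from it without further libraries.

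Without mitochondrial, ribosomal, haemoglobin, sex-linked and predicted genes and RIKEN clone names, with which there were 23, a set of 12 genes passed the size rule the same way in each of 4 classes outside the lineage (stroma-like, endothelial-like, ureteric bud and collecting duct-like and macrophage-like), 5 higher, among them the chaperone gene Hspa5, and 7 lower, among them Zfp787. Reads shared between near-identical copies may account for some of them: the summed log2 ratio lay within 0.2 of 0 for 2 of 3 pairs (Tpm3 with Tpm3-rs7, -0.18, and Eif3j1 with Eif3j2, -0.14, against -0.26 for Rnaset2a with Rnaset2b), while an unchanged partner would have given 0.35, 0.25 and -0.77. The bound set in advance against sharing could not have been reached by the Tpm3 and Eif3j pairs, so that test could exclude less than intended. A genetic background that differs between the animals stays open: 10 of the 12 genes also passed the rule in progenitor-like cells, and without sequence variants or further animals this cannot be told apart from genotype. Whether genes that differ group by position was not tested. Among the named genes, Ifi27l2a and Serpina6 (lower) and Serpina1b (higher) lie on chromosome 12 between 103433873 and 103738189. Ralyl, Kcnmb2, Rbm46, S100a6 and Hsd3b2, each higher where named, share chromosome 3 with Tet2, and Trh shares chromosome 6 with Tet3. Those on chromosome 3 start between 13471655 and 98711107, while Tet2 starts at 133463677. Chromosome 14, which holds neither targeted gene, also carries several named genes: Rnase4, Rpgrip1, Fitm1, Egr3 and Tpm3-rs7, some higher and some lower. Sharing a chromosome with a targeted gene therefore does not set these genes apart.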

How the results depend on the processing

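These tests were chosen after the data were seen: the automatic doublet threshold, the mixed cluster counted as progenitors, all on the cycling share, all on shares other than the progenitor, committed and stroma ones, and all on gene counts other than those of progenitor-like cells. Of 271 alternatives for the main results (73 of them not planned), 208 left the value within its counting interval (or a count within 1.5 times), 60 moved it and 3 reversed it, and 243 kept its sign. Of 205 alternatives for other values (65 not planned), 163, 40 and 2 did so. Counts of genes, with 15, 15, 15 and 14 of the 271 alternatives, cannot change sign, so the 243 include them by construction. A value was called reversed only where its interval in the report left out 0. Other changes of sign were counted as moved or as within the interval. Tet3 in nephron progenitor-like cells ranged from -1.25 to -1.01 and Tet2 from -0.40 to -0.19 (log2, floxed over control). Except where a cause is given, the cause was not tested. No paired analysis was possible because each genotype has 1 library. Depth limits the classes with few cells, and more libraries, not deeper ones, would be needed to separate genotype from animal.

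Log2 ratios of shares in the report were -0.29 for nephron progenitor-like, -0.07 for committed nephron-like and 0.04 for stroma-like cells. With the looser cell filter the progenitor share was -0.54 and the stroma share -0.40; with the stricter filter the committed share was -0.24. With the 10000 deepest barcodes, which cut the libraries at unlike depths, the shares were -1.06 (progenitor), -0.67 (committed), 0.40 (stroma) and 0.43 (podocyte-like, reversed from -0.31). With doublets kept they were -0.14 (progenitor) and 0.13 (stroma), and with the automatic doublet threshold -0.39 (progenitor), -0.29 (committed) and -0.064 (stroma). With Leiden resolution 0.5 they were -0.14 (progenitor) and -0.24 (committed), and with floxed cells mapped to control clusters 0.087 (committed) and 0.12 (stroma). Within the nephron lineage alone, which changes the denominator, they were -0.18 (progenitor) and 0.036 (committed). Cells with at least 2 Six2 UMIs, a count that depends on depth, gave -0.67. For proximal tubule-like cells (-0.03 in the report) the share was 0.34 with the stricter and -0.60 with the looser filter, -0.64 with the 10000 deepest barcodes, -0.21 with doublets kept and -0.67 with mapped floxed cells. For loop of Henle and distal tubule-like cells (0.77 in the report) it was 1.15 with the stricter and 0.079 with the looser filter, 0.98 at resolution 0.5 and 0.45 with mapped floxed cells.

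Counts of genes past the size rule were 181 in progenitor-like, 146 in committed nephron-like, 254 in proximal tubule-like and 187 in stroma-like cells. In the same order they were 44, 40, 64 and 54 at 2-fold, 649, 558, 627 and 827 with no CPM minimum, and 56, 51, 96 and 56 at 100 CPM or more, by construction of these rules. Cells thinned to equal UMIs, with fewer counts, gave 115 (progenitor), 83 (committed) and 116 (proximal tubule). Relative to stroma-like cells the counts were 27, 70 and 140, of which 16, 23 and 49 were among the genes counted in the report, and the higher genes made up 91.4% in place of 63.0% (committed) and 73.6% in place of 45.3% (proximal tubule). The TMM factors shifted log2 ratios in progenitor-like cells by -0.06 and gave 89 higher and 94 lower genes there, in place of 111 and 70. In proximal tubule-like cells, with 115 higher and 139 lower in the report, TMM gave 133 and 116, the stricter filter 110 and 106, and the looser filter 124 and 118. At 2-fold, 33.3% of the stroma genes were higher, in place of 44.4%.

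Medians of gene lists in progenitor-like cells moved as follows. With the 10000 deepest barcodes they were 0.10 (progenitor regulators), 0.14 (commitment), 0.17 (p53 and apoptosis) and 0.020 (proliferation, reversed from -0.31), and the cycling share was -0.35 in place of -0.55. Proliferation stood at -0.38 with the looser and -0.38 with the stricter filter. With doublets kept, Wnt stood at 0.10 and tubule injury at -0.32. Resolution 0.5 gave 0.47 (commitment), 0.30 (Notch), -0.00022 (DNA methylation enzymes) and -0.10 (proliferation). The automatic doublet threshold gave 0.55 (commitment), 0.30 (Notch) and -0.38 (proliferation). Thinned cells gave 0.13 (Wnt), -0.12 (glycolysis and hypoxia) and -1.14 (interferon response). TMM gave -0.068 (progenitor regulators), -0.37 (proliferation) and -0.11 (oxidative phosphorylation). Without cycling cells the medians were 0.51 (commitment), 0.32 (Notch), 0.11 (FGF), 0.032 (DNA methylation enzymes, reversed from -0.15) and 0.26 (proliferation, reversed), and proliferation in stroma-like cells was 0.22 (reversed from -0.23); the cells left out were chosen by proliferation genes.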

Other observations

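The gene values in this part were chosen after the data were seen. Loop of Henle and distal tubule-like cells, a class whose share was 1.70-fold higher in the floxed library but nearly equal with the looser cell filter (4.30% and 4.54%), had 92 genes higher and 147 lower. Slc12a3, the thiazide-sensitive sodium chloride cotransporter of the distal tubule, stood at 120 CPM in the control and 46.1 CPM in the floxed library, and Slc12a1, the cotransporter of the thick ascending limb, at 1494 and 1609 CPM. Slc12a1 was 1 of 2 loop of Henle markers with a positive log2 ratio. The median of those markers was -0.63 with 3 of 6 lower, Umod among them (438 and 173 CPM). Distal tubule markers had a median of -0.08 with 1 of 6 lower. Calb1, a calcium-binding protein of the distal tubule, stood at 888 and 401 CPM. The class was a single cluster in which loop of Henle and distal tubule cells were not separated, so these levels rest on their mix. Slc12a1 and Umod were among the leading genes of that cluster.

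Ureteric bud and collecting duct-like cells, which Six2Cre should not reach, had 144 genes higher and 101 lower. Wnt11, which marks ureteric tips, stood at 36.7 CPM in the control and 18.2 CPM in the floxed library, and Ret, the receptor for Gdnf, at 51.0 and 40.3 CPM. Hsd11b2, which inactivates glucocorticoids in principal cells, stood at 46.8 and 133 CPM, and the water channel gene Aqp2 at 2680 and 2446 CPM. The intercalated cell gene Atp6v1g3, a proton pump subunit, stood at 102 and 51.2 CPM.

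Genes that differed in progenitor-like cells beyond their difference in stroma-like cells included Pnp, a purine nucleoside phosphorylase (41.9 and 86.1 CPM), and Celf2, a splicing regulator (13.8 and 32.2 CPM). Cxcl10, an interferon-inducible chemokine, had 10 and 84 UMIs in podocyte-like cells (log2 ratio 4.07), the opposite direction to its log2 ratio of -2.52 in stroma-like cells. Hmox1, which encodes haem oxygenase 1, stood at 171 and 31.8 CPM in proximal tubule-like cells, and the metallothionein gene Mt1 at 1052 and 2712 CPM.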
